A study of Homo sapiens with 28 samples.

How the data were processed

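The 28 samples were grouped by their titles and antibody labels. Of these, 16 formed 8 immunoprecipitated groups of 2 (ZHX2, CTCF and H3K27ac in normoxia and in hypoxia, and Flag in hypoxia with WT or PA ZHX2), and 12 had no antibody. Among the latter, 4 samples are titled Flag but give no antibody, per the labels, and were kept apart from the Flag groups. Per the labels' protocols, cells were fixed with formaldehyde (hypoxic cells inside the hypoxia chamber) and libraries were made with a commercial DNA kit.

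Per the submitters' processing notes, cutadapt, Bowtie2 and MACS2 were used with the build GRCh38 (hg38), and no versions are named there. The authors deposited 1 peak list per immunoprecipitated group. Whether the 2 samples of a group were pooled, how the inputs were used and how many reads were sequenced is not given in the sources used here, so the precision of any single peak is unknown. ZHX2 and CTCF lists are narrow peaks with a summit, H3K27ac lists are broad peaks without one, and Flag lists hold positions alone. The score of a peak, its fold enrichment (a ratio over background) and its −log10 p and −log10 q are the authors' values as deposited. The score column was 10 times the deposited −log10 q, without its decimals. These values were used only to describe, rank or filter peaks within a list. The lowest −log10 q was 1.30 in both ZHX2 lists, 5.00 and 5.09 in the CTCF lists and 3.49 and 3.46 in the H3K27ac lists, so thresholds differed between antibodies and numbers of peaks are not compared between them.

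Peaks on chromosomes 1 to 22 and X were kept. Peaks overlapping by at least 1 bp were called shared, and hypoxia-only, normoxia-only, WT-only and PA-only peaks are those with no such overlap in the partner list. Shares have 95% Wilson intervals, which cover counting error over peaks only. Co-location was tested against 1000 random placements of each peak on its own chromosome, with lengths taken as the highest coordinate in the lists and assembly gaps not excluded (one-sided, smallest p 0.000999). The alternative drew 100 placements within the merged regions of all 8 lists (smallest p 0.00990). For hypoxia-only ZHX2 peaks at WT Flag peaks, 100 placements within H3K27ac regions and a comparison of 200 bp cores with those of hypoxia-only CTCF peaks, with and without a ZHX2 peak, were added after seeing the data. Change classes were compared with two-sided Fisher exact tests adjusted over 19 tests by the Benjamini-Hochberg method. Neighbouring peaks are not independent, so these p-values are too small for the number of separate sites.

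No genome sequence or exon annotation was used here. Gene positions came from a RefSeq gene table of GRCh38.p14 that gives the start and end of each gene without strand, so the planned promoter window was replaced by 1 kb around either annotated end, and gene-end peaks include peaks at transcript ends. Entries on unplaced or alternate scaffolds were left out, leaving 19821 protein-coding genes. Motifs, exons and introns were not analysed here. The 17 gene lists were fixed before the data were examined: hypoxia-induced genes, glycolysis, oxidative phosphorylation, invasion with matrix, NF-kappaB, luminal identity, basal or myoepithelial markers, immune and stromal markers, chromatin looping, hypoxia signalling with the ZHX family, cell cycle, cytosolic ribosomal proteins, zinc finger genes, HOX genes, clustered protocadherins, olfactory receptors and replication-dependent histones. All members asked for were found by symbol or older symbol. Each share was compared with all protein-coding genes by a two-sided Fisher exact test adjusted over 136 tests, with 10000 random lists of equal size, and with genes matched for a normoxia H3K27ac peak.

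Genes were named by a rule fixed at the same time: at gene ends, the 10 strongest peaks of the normoxia-only or WT-only class and the 5 strongest of the other class by the authors' fold (by width for Flag), up to 4 members per gene list and class, and ZHX2, CTCF, HIF1A, EPAS1, VHL, CA9, VEGFA, SLC2A1, EGLN3, NDRG1, ESR1, GATA3, MYC and CCND1. Members counted in 1 list alone, and the peaks inside HIF1A, NAT10, NEK9, GSE1, BCOR, ANKRD11, CBFA2T3, MED13L, DLG2, RASA3 and KDM4B and at immunoglobulin and T cell receptor segments, were named after their values were seen. Some Flag peaks that the rule selects are not reported here.

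Alternatives fixed beforehand covered the overlap (50% of the shorter peak, or summits or midpoints within 250 bp), the upper 50% of the lists by score, lists of equal length, all contigs, a −log10 q of at least 5, merged peaks, odds ratios within 10 strata of score, peaks reduced to 200 bp, windows of 3 kb and all annotated genes. The steps were tested on simulated data. A planted overlap of 30% of 20000 peaks, from which overlapping peaks were then dropped, was recovered as 29.8% after correction for random placement. The shares in the results carry no such correction. A stratified odds ratio of 2 was recovered as 2.13. The placement test called 0 of 20 lists of 3000 random positions. Such lists are random like the placements themselves, so they do not test peaks that cluster. The gene list tests were not simulated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.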

Results

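Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used in T47D, an established luminal breast cancer cell line, to map where ZHX2, CTCF and acetylated histone H3 lysine 27 (H3K27ac) lay on chromatin in normoxia and in hypoxia. ZHX2 is a zinc finger and homeobox protein, CTCF is a DNA-binding protein found at chromatin loop anchors, and H3K27ac marks active promoters and enhancers. A second set of cells, all in hypoxia, carried Flag-tagged ZHX2 in a wild-type (WT) or a mutant form that the labels name PA, and was immunoprecipitated for Flag. The 16 immunoprecipitated samples formed 8 groups of 2, and another 12 samples had no antibody. Each of the 8 groups had 1 peak list and no values per replicate, and read depth was not given in the sources used here. Differences between conditions or proteins therefore had no replicate check, and all of them are given as values. Intervals are 95% Wilson intervals over peaks and cover counting error only, and each p-value compares peaks or genes within these lists, not conditions. Coordinates are those of GRCh38. A gene was said to hold a peak when a peak lay within 1 kb of either of its annotated ends, and 19821 protein-coding genes were examined.

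The first comparison asked where ZHX2 lay in hypoxia and not in normoxia. In hypoxia ZHX2 peaks lay at the ends of 11154 protein-coding genes (56.3%), and in normoxia at the ends of 5881 (29.7%). Of these genes 5515 held a peak in both lists, 5639 in the hypoxia list alone and 366 in the normoxia list alone. Genes with a hypoxia-only peak included BNIP3L, a mitophagy receptor, ENO1, a glycolytic enolase, MXI1, an antagonist of MYC, and MYC itself. The hypoxia list held 32343 peaks covering 15.1 Mb and the normoxia list 14586 peaks covering 5.84 Mb, a ratio of 2.22 in number. At a −log10 q of at least 5 the lists held 22013 and 9132 peaks, a ratio of 2.41.

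Of the hypoxia ZHX2 peaks, 8878 overlapped a normoxia peak (27.4%, interval 26.97 to 27.9%) and 23465 were hypoxia-only. Of the normoxia peaks, 9124 overlapped a hypoxia peak (62.6%, 61.8 to 63.3%) and 5462 were normoxia-only. Sharing followed the authors' peak score. In the hypoxia list 7.97% of the lowest decile by score was shared, 81.2% of the highest decile, and 321 of the 325 peaks in the top percent. With both lists reduced to equal length, 45.6% of the hypoxia peaks were shared, and with only the upper 50% of the hypoxia list, 43.0%. Hypoxia-only peaks had a median width of 304 bp, and shared peaks of the same list 592 bp.

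**Figure D1:**
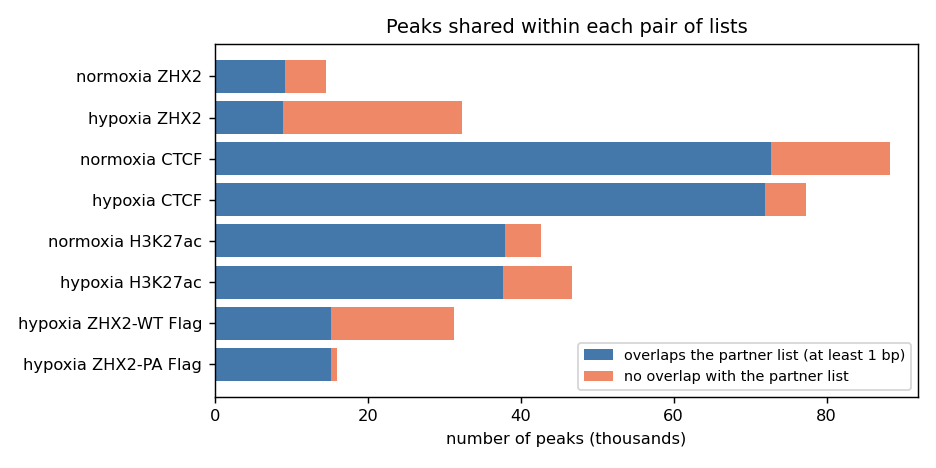
Number of peaks, in units of 1000, in each of the 8 lists on chromosomes 1 to 22 and X, divided into peaks that overlap the partner list by at least 1 bp (blue) and peaks that do not (orange); partners are normoxia and hypoxia for each antibody, and WT and PA for Flag. The hypoxia ZHX2 list has 23465 peaks without a partner, and the PA Flag list has 856.

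The hypoxia-only ZHX2 peaks with the highest authors' fold enrichment at gene ends lay at TMEM80 (chromosome 11, 695633 to 696198, fold 11.6), HIVEP2 (chromosome 6, 142946276 to 142946723, fold 11.5), MTMR3 (fold 10.4), BCL11A (fold 9.79) and RGPD6 (fold 9.65). The normoxia-only peaks at protein-coding gene ends were led by a peak at the shared ends of GAPDH and IFFO1 (chromosome 12, 6537599 to 6538294, fold 12.5), followed by CD74 (chromosome 5, 150401738 to 150402281, fold 9.71), TENM2 (7.75), ACTB (7.55), HSPB8 (6.88), CALR (6.79), LRRC4 (6.43), FOXE1 (6.43), NHLRC4 with PIGQ (6.33) and TPT1 (6.19). GAPDH, ACTB, CALR and TPT1 are among the most abundantly transcribed genes of many cell types, and CD74 is the invariant chain of antigen-presenting cells. GAPDH, ACTB, HSPB8, CALR (best fold 8.15), LRRC4 and NHLRC4 also held other peaks in the hypoxia ZHX2 list, while CD74 and FOXE1 held none. HIVEP2 also held a normoxia ZHX2 peak (fold 4.98, higher than 87.1% of that list). The normoxia list also had 24 peaks on immunoglobulin and T cell receptor gene segments, of which all 24 were normoxia-only, while the hypoxia list had 1. Inside the HIF1A gene both lists had 12 peaks of their own top percent by score, with folds of 82.1 to 376 in the normoxia list and 33.2 to 146 in the hypoxia list, and of the 12 hypoxia peaks 0 overlapped a WT Flag peak and 5 a PA Flag peak.

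Among genes known to be induced by hypoxia, 28 of 36 held a ZHX2 peak in hypoxia and 9 in normoxia. These 9 held peaks in both lists, 19 in the hypoxia list alone and 0 in the normoxia list alone. The hypoxia-only peaks with the highest fold lay at BNIP3L (chromosome 8, 26383478 to 26383875, fold 9.18), ENO1 (chromosome 1, 8877806 to 8879321, fold 7.11), MXI1 (fold 7.10) and STC2 (fold 6.92), and a normoxia-only peak lay at DDIT4 (fold 4.49). The share in hypoxia, 77.8%, was above that of all protein-coding genes (odds ratio 2.72, two-sided Fisher exact test, exact adjusted p = 0.0252 with Benjamini-Hochberg adjustment over 136 tests of 17 lists in 8 peak lists; p = 0.0172 adjusted over the list alone) and lay at the 99.6th percentile of 10000 random lists. Against genes matched for a normoxia H3K27ac peak it did not pass (odds ratio 1.39, exact adjusted p = 0.763). In normoxia the share was 25% (exact adjusted p = 0.754).

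Among genes of luminal breast identity, 17 of 20 held a ZHX2 peak in hypoxia and 8 in normoxia. The 9 in the hypoxia list alone included GATA3, a luminal transcription factor, PGR, the progesterone receptor, and MYB, whose hypoxia-only peak (chromosome 6, 135180355 to 135181466) had a fold of 5.80. Hypoxia-only peaks also lay at XBP1 (fold 5.79), TFAP2A (fold 5.76) and GREB1 (fold 5.22), and normoxia-only peaks at GREB1 (fold 3.28), KRT8 (fold 2.39) and KRT19 (fold 2.23). The GREB1 peaks lay side by side (chromosome 2, 11481745 to 11482518 in hypoxia and 11482624 to 11482886 in normoxia), so they do not show separate sites. KRT8 and KRT19 also held hypoxia ZHX2 peaks, with best folds of 4.53 and 3.25. The best normoxia peak at XBP1 had a fold of 10.1, higher than 98.1% of that list. The luminal share in hypoxia passed the test against all genes (odds ratio 4.41, exact adjusted p = 0.0259) and not against matched genes (odds ratio 1.90, exact adjusted p = 0.741). In normoxia it did not pass at 1 kb (exact adjusted p = 0.416) and passed within 3 kb (13 of 20, exact adjusted p = 0.0194). Of the immune and stromal markers 3 of 16 held a ZHX2 peak in hypoxia, below all genes (exact adjusted p = 0.00993, and 0.528 against matched genes), and 1 of 16 in normoxia (exact adjusted p = 0.0948). Of the basal or myoepithelial markers 4 of 11 did so in hypoxia and 1 of 11 in normoxia (exact adjusted p = 0.318 and 0.278).

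Other groups held ZHX2 peaks in normoxia at more than the 29.7% of all genes. HOX genes, the developmental homeobox clusters, had 26 of 39 (66.7%, odds ratio 4.76, exact adjusted p = 1.71e-05, and 1.87e-10 against matched genes). Neighbours in a HOX cluster are not independent, so these p-values are too small. HOXC10 and HOXC11, for example, had the same best H3K27ac fold in normoxia (47.1). In hypoxia 21 of the 39 held a peak (53.8%, exact adjusted p = 0.785), and HOXA2, HOXA3, HOXA5, HOXA9, HOXB9 and HOXD8 held one in the normoxia list alone against HOXB13 in the hypoxia list alone. The normoxia-only peak at HOXD8 (chromosome 2, 176129988 to 176130723) had a fold of 4.73. Genes of chromatin looping, such as CTCF and the cohesin subunit RAD21, had 12 of 17 in normoxia (70.6%, exact adjusted p = 0.00214) and 15 in hypoxia (88.2%, exact adjusted p = 0.0165), with WAPL, LDB1 and ZNF143 in the hypoxia list alone. Clustered protocadherins, neuronal adhesion genes, had 27 of 53 in normoxia (exact adjusted p = 0.00414) and 34 in hypoxia (exact adjusted p = 0.353). Within 3 kb the hypoxia share passed as well (42 of 53, odds ratio 2.44, exact adjusted p = 0.0179). Members of the gamma cluster share an annotated end, so they are not independent in either condition or window. Of the 53 members 23 held a normoxia-only peak. PCDHGA1, PCDHGA10, PCDHGA11 and PCDHGA12 held the same peak (chromosome 5, 141512577 to 141512781, fold 3.21). Cytosolic ribosomal protein genes had 44 of 81 in normoxia (exact adjusted p = 2.15e-05) and 68 in hypoxia (exact adjusted p = 1.32e-06), with the strongest hypoxia-only peak at RPL13A (fold 9.23). Normoxia-only peaks lay at RPS7 (fold 5.04), RPL11 (fold 4.13), RPLP0 (fold 3.26) and RPL8 (fold 3.24), and RPL10L, RPL11 and RPS7 held a peak in the normoxia list alone.

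Oxidative phosphorylation genes had 12 of 23 with a ZHX2 peak in normoxia (exact adjusted p = 0.0464, and 0.0856 within 3 kb) and 20 in hypoxia (exact adjusted p = 0.00694), COX4I1 and ATP5F1B being among the 8 in the hypoxia list alone. Replication-dependent histone genes had 29 of 68 (exact adjusted p = 0.0467) and 52 (exact adjusted p = 0.00284). Neighbouring histone genes can hold the same peak, as H2AC15 and H2BC15 did in hypoxia, so they are not independent. Against matched genes, HOX genes and clustered protocadherins passed in normoxia (exact adjusted p = 0.00791 for the latter). The protocadherin test counts the same peak for several gamma members, and neighbouring HOX genes are not independent. Looping, ribosomal protein, oxidative phosphorylation and histone genes did not pass against matched genes in normoxia (0.0637, 0.0637, 0.600 and 0.710) or in hypoxia (0.753, 0.710, 0.760 and 0.753). Olfactory receptors, which are silent in breast cells, lay far below all genes, with 2 and 7 of 389 (exact adjusted p = 2.63e-55 and 8.31e-126). For the remaining lists neither share passed the test against all genes at 1 kb, but within 3 kb of a gene end glycolysis genes (11 of 17, exact adjusted p = 0.0412) and genes of hypoxia signalling and the ZHX family (9 of 13, exact adjusted p = 0.0364) passed in normoxia. Glycolysis genes had 8 and 12 of 17, with HK2, GPI, ALDOA, ENO1 and LDHA in the hypoxia list alone and TPI1 in the normoxia list alone. Invasion and matrix genes had 6 and 16 of 28, including LOX, a collagen-crosslinking enzyme (fold 3.93), and ITGB1 (fold 4.97). NF-kappaB pathway genes had 7 and 14 of 20, with the strongest hypoxia-only peak at NFKBIE, an inhibitor of the pathway (chromosome 6, 44265400 to 44265836, fold 7.85), and normoxia-only peaks at ICAM1 (fold 3.04) and NFKB2 (fold 2.75). ICAM1 and NFKB2 also held hypoxia ZHX2 peaks, and NFKBIE a normoxia ZHX2 peak (best fold 3.36). Genes of hypoxia signalling and the ZHX family had 7 and 10 of 13, with EPAS1, EGLN2 and HIF1AN in the hypoxia list alone. Cell cycle genes had 8 and 16 of 26, and zinc finger genes 134 and 308 of 510. Against matched genes the hypoxia odds ratios were 0.382 for cell cycle genes (exact adjusted p = 0.0637) and 0.564 for zinc finger genes (2.96e-07), and the normoxia odds ratio of zinc finger genes was 0.609 (1.36e-05).

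**Figure D2:**
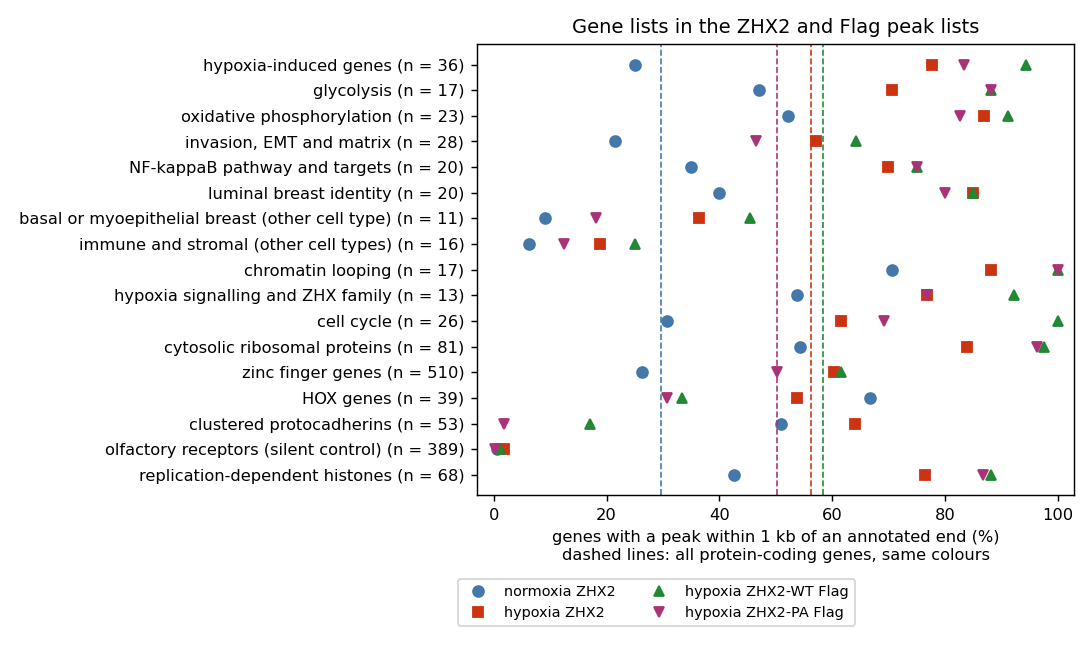
Share of the genes in each of the 17 lists (number of members in brackets) that hold a peak within 1 kb of an annotated end, in the normoxia ZHX2, hypoxia ZHX2, WT Flag and PA Flag lists; dashed lines give the share of all protein-coding genes in the same colours (29.7%, 56.3%, 58.5% and 50.2%). HOX genes lie above the normoxia ZHX2 line at 66.7% and below the WT and PA Flag lines, and olfactory receptors lie near 0.

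The next comparison asked whether ZHX2 lay with CTCF and H3K27ac. In hypoxia 45.6% of ZHX2 peaks overlapped a CTCF peak (45.1 to 46.2%) and 72.9% an H3K27ac peak (72.4 to 73.4%), against means of 3.26% and 4.88% for 1000 random placements of the same peaks on their chromosomes (13.99 and 14.9 times as many; one-sided permutation of positions, p = 0.000999 for each, the smallest these placements can give). In normoxia the shares were 43.6% (42.8 to 44.4%) and 56.7% (55.8 to 57.5%), against 3.22% and 4.53% (13.5 and 12.5 times, p = 0.000999 each by permutation). When the ZHX2 peaks were instead placed at random within the merged regions of all 8 lists, the hypoxia shares were 1.19 and 1.11 times the placed mean. The normoxia share at CTCF was then 1.14 times, and that at H3K27ac 0.907 times. The placed means at H3K27ac were already 65.5% in hypoxia and 62.5% in normoxia, which limits how far these ratios can exceed 1. Peaks with both CTCF and H3K27ac made up 40.5% of the hypoxia ZHX2 list and 37.3% of the normoxia list, peaks with H3K27ac alone 32.5% and 19.4%, and peaks with neither 21.9% and 37.0%. Among ZHX2 peaks that overlapped CTCF, the median distance between summits was 141 bp in hypoxia and 174 bp in normoxia.

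Hypoxia-only ZHX2 peaks lay mostly where H3K27ac was present in both conditions. Of the 23465 peaks, 68.2% (67.6 to 68.8%) lay on H3K27ac peaks of both lists, 2.92% (2.71 to 3.14%) on H3K27ac of the hypoxia list alone, and 27.8% on neither. For CTCF 36.5% lay on peaks of both lists, 2.81% on the hypoxia list alone and 55.6% on neither. Compared with shared ZHX2 peaks of the hypoxia list, hypoxia-only peaks overlapped CTCF less often (39.3% against 62.4%, odds ratio 0.390, interval 0.371 to 0.410, exact adjusted p = 1.26e-303 over 19 class tests, two-sided Fisher exact test). They also overlapped H3K27ac less often (71.1% against 77.8%, odds ratio 0.701, 0.662 to 0.742, exact adjusted p = 8.77e-35). Within deciles of the authors' score the odds ratio at CTCF was 0.685, and that at H3K27ac turned to 1.61. Normoxia-only ZHX2 peaks overlapped CTCF in 13.8% and H3K27ac in 21.4%, against 61.4% and 77.7% of shared normoxia peaks (odds ratios 0.101, 0.0924 to 0.110, and 0.0780, 0.0719 to 0.0846), and with peaks reduced to 200 bp the odds ratios were 0.258 and 0.343. Of shared hypoxia peaks 52.6% lay near a protein-coding gene end, of hypoxia-only peaks 29.8%, and of normoxia-only peaks 13.2%.

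**Figure D3:**
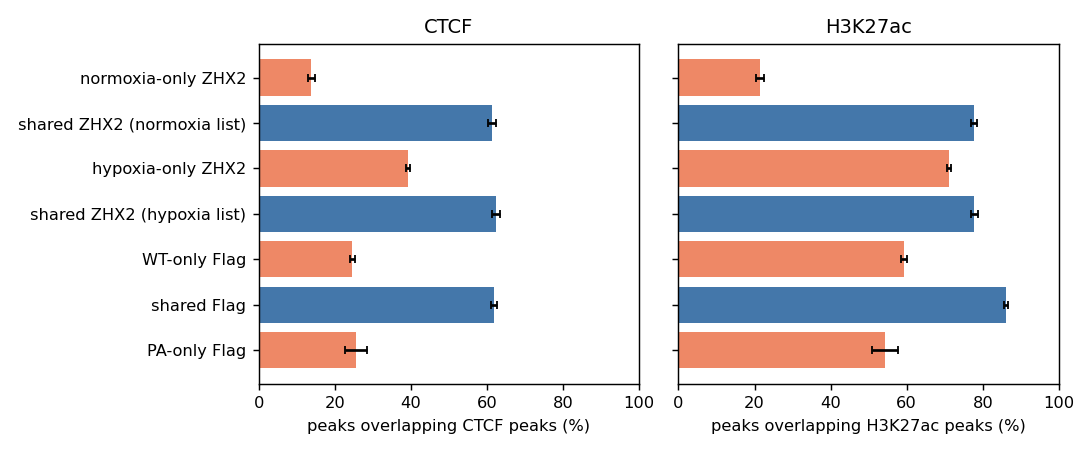
Percent of peaks in each class that overlap a CTCF peak (left) or an H3K27ac peak (right) of the same condition, with 95% Wilson intervals over peaks; orange bars are peaks found in 1 list of a pair, blue bars are shared peaks. Normoxia-only ZHX2 peaks have the lowest shares, 13.8% for CTCF and 21.4% for H3K27ac.

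CTCF itself was compared between normoxia and hypoxia at the same genes. CTCF peaks lay at the ends of 11245 protein-coding genes in both conditions, at 1029 in normoxia alone and at 567 in hypoxia alone. The normoxia-only CTCF peak with the highest fold at a gene end lay at PGK1, the gene of the glycolytic enzyme phosphoglycerate kinase (chromosome X, 78103766 to 78104366, fold 21.0). PGK1 held no CTCF peak in the hypoxia list, where its best ZHX2 peak had a fold of 42.5, higher than 99.9% of that list; in the normoxia list its ZHX2 peak had a fold of 2.99, higher than 31.1% of that list. The other genes named by this rule were PLPP2 (15.1), NDST3 (14.3), STAT3 (14), STX8 (13.7), PIK3AP1 (13.4), FGF3 (13.2), USP32 with CHCT1 (13.0), SH2D6 (12.8) and SLX1A (12.7). Among them PLPP2, NDST3 and PIK3AP1 also held CTCF peaks in hypoxia, while FGF3 held none. In the other direction the hypoxia-only CTCF peaks with the highest fold at gene ends lay at XBP1, a transcription factor of the unfolded protein response (chromosome 22, 28800288 to 28800538, fold 9.96), GNB1 (9.56), the shared ends of HSPD1 and HSPE1, mitochondrial chaperones (9.09), EIF2AK3, the stress kinase PERK (8.69), and TFIP11 (8.69). GNB1, HSPD1 and HSPE1 also held CTCF peaks in normoxia, while EIF2AK3 held none.

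The hypoxia CTCF list held 77334 peaks covering 52.7 Mb and the normoxia list 88248 covering 50.5 Mb, a ratio of 0.876 in number. In the hypoxia list 93.0% of peaks were shared (92.9 to 93.2%) and 5382 were hypoxia-only. In the normoxia list 82.3% were shared (82.1 to 82.6%) and 15576 were normoxia-only. All of the highest decile by score was shared in each list. Of the hypoxia-induced genes, PFKFB4 and MXI1 held a CTCF peak in hypoxia alone and PGK1, EGLN3 and TMEM45A in normoxia alone. Of the luminal genes XBP1 and TFAP2A did so in hypoxia alone, and of the basal genes KRT14 and KRT17 in normoxia alone. Clustered protocadherins, whose promoters are known CTCF sites, held CTCF peaks at 51 of 53 members in normoxia (exact adjusted p = 4.34e-08) and 52 in hypoxia (exact adjusted p = 6.16e-10). The gamma members share an annotated end and are not independent. PCDHGA1, PCDHGA10, PCDHGA11, PCDHGA12 and PCDHGB6 had the same best CTCF fold (214.6 in normoxia and 186.3 in hypoxia).

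Hypoxia-only CTCF peaks overlapped a hypoxia ZHX2 peak in 16.6% of cases (15.7 to 17.7%) and shared CTCF peaks in 18.2% (17.9 to 18.5%), an odds ratio of 0.895 (0.831 to 0.964, exact adjusted p = 0.00332, two-sided Fisher exact test). The direction was not stable. The odds ratio was 1.51 when summits within 250 bp counted as overlap, 1.69 with lists of equal length and 1.495 with every peak reduced to 200 bp, but 0.412 within deciles of the score and 0.354 in the upper 50% of both lists. Normoxia-only CTCF peaks overlapped a normoxia ZHX2 peak in 3.53% of cases and shared ones in 7.72% (odds ratio 0.437, 0.400 to 0.478, exact adjusted p = 1.33e-89), but among the upper 50% of the normoxia CTCF list by score, where few normoxia-only peaks remain, the odds ratio was 4.43 (exact p = 0.327). It was 0.269 within deciles of the score and 0.729 with summits within 250 bp. Hypoxia-only CTCF peaks lay on H3K27ac in 33.8% of cases and shared ones in 30.3% (odds ratio 1.18, exact adjusted p = 8.20e-08), which turned to 0.591 within deciles of the score and was 1.78 with lists of equal length. Normoxia-only CTCF peaks did so in 23.4% and shared ones in 28.8% (odds ratio 0.756, exact adjusted p = 3.62e-43), which turned to 1.41 in the upper 50% of both lists and was 0.433 within deciles of the score.

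H3K27ac was compared in the same way. Among 36 hypoxia-induced genes, CA9, a carbonic anhydrase of the hypoxia response, and LOX held an H3K27ac peak in hypoxia alone, 32 held one in both conditions and 0 in normoxia alone. The hypoxia-only peaks lay at LOX (chromosome 5, 122076931 to 122078605, fold 4.42), CA9 (chromosome 9, 35673381 to 35674254, fold 3.503), ANGPTL4 (fold 3.31) and VEGFA (fold 3.14), and among glycolysis genes at ENO2 (fold 5.53), LDHA (fold 2.98) and PGAM1 (fold 2.69), where ANGPTL4, VEGFA, ENO2, LDHA and PGAM1 held other H3K27ac peaks in normoxia. With 34 of 36 genes (94.4%) the hypoxia-induced list exceeded the 65.2% of all genes in the hypoxia H3K27ac list (odds ratio 9.08, exact adjusted p = 0.000283, two-sided Fisher exact test), and in normoxia, with 32 of 36, it exceeded all genes as well (odds ratio 4.44, exact adjusted p = 0.00435). The test in hypoxia against genes matched for a normoxia H3K27ac peak (odds ratio 27.2, exact adjusted p = 0.00817) rests on CA9 and LOX. Of the luminal genes, TFF1 held a peak in hypoxia alone, and all 20 held one in hypoxia. Over all protein-coding genes 12643 held H3K27ac in both conditions, 288 in hypoxia alone and 115 in normoxia alone.

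The hypoxia H3K27ac list held 46713 peaks covering 101.6 Mb and the normoxia list 42586 covering 97.0 Mb, a ratio of 1.10 in number. Of the hypoxia peaks 80.6% were shared (80.3 to 81.0%) and of the normoxia peaks 89.1% (88.8 to 89.4%). At gene ends the strongest hypoxia-only peaks lay at TH, the gene of tyrosine hydroxylase (chromosome 11, 2167107 to 2171098, fold 8.25), GH1 (7.19), VLDLR, a lipoprotein receptor (6.77), MAD2L2 (5.86) and APOBEC3C with APOBEC3D (5.65). The strongest normoxia-only peaks at gene ends lay at MCTS1 (5.84), SYN1 (5.82), IL22RA1 (5.03), RPS6KL1 (4.99), CDC42EP5 (4.96), TNFAIP6 (4.49), VSX1 (4.35), TMEM132B (4.33), SYNM (4.31) and LOC107987025 (4.28). Of these, MCTS1, IL22RA1 and CDC42EP5 also held H3K27ac in hypoxia, with best folds of 9.75, 3.53 and 20.7, while LOC107987025 held none. Hypoxia-only H3K27ac peaks were short, with a median width of 450 bp against 1673 bp for shared peaks, and 5.66% overlapped a hypoxia ZHX2 peak against 42.5% of shared peaks (odds ratio 0.0812, 0.0741 to 0.0890). At CTCF the shares were 18.5% and 44.6% (odds ratio 0.283, 0.267 to 0.299). Normoxia-only H3K27ac peaks overlapped normoxia ZHX2 in 2.09% and CTCF in 17.6%, against 17.4% and 47.7% of shared peaks (odds ratios 0.101, 0.0825 to 0.124, and 0.234, 0.217 to 0.253). Within deciles of the score these differences were much smaller or turned, with odds ratios of 0.713 and 1.13 for hypoxia-only peaks and 0.991 and 0.825 for normoxia-only peaks.

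The Flag lists asked how the PA form of ZHX2 differed from WT in hypoxia. WT peaks lay at the ends of 11590 protein-coding genes (58.5%) and PA peaks at 9943 (50.2%). Of these 9848 were common, 1742 held a WT peak alone and 95 a PA peak alone. Among hypoxia-induced genes CA9, SLC2A3, BNIP3 and KDM4B held a WT peak alone and none a PA peak alone. Of the 34 hypoxia-induced genes with a WT peak 30 also held a PA peak, and of all 11590 genes with one 9848 did. WT-alone genes were therefore no more frequent among hypoxia-induced genes than among all genes. Among cell cycle genes MKI67, CCNE1, CDC25A, AURKB, BUB1, MCM3, E2F1 and E2F2 held a WT peak alone and none a PA peak alone. The WT list held 31278 peaks covering 36.1 Mb and the PA list 16019 covering 27.7 Mb, a ratio of WT to PA of 1.95 in number and 1.30 in covered length.

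Of the PA peaks 94.7% overlapped a WT peak (94.3 to 94.99%), and of the WT peaks 48.5% overlapped a PA peak (47.9 to 49.0%), leaving 16115 WT-only and 856 PA-only peaks. All 15163 shared peaks had identical start and end positions in both lists, whereas at most 6 peaks did so in any normoxia and hypoxia pair. The overlaps and the WT-only and PA-only classes therefore describe which of these intervals each list holds, and how the lists were derived is not given in the sources used here. These lists carried no score or fold. By width, the WT-only peaks at gene ends that ranked highest included ENO2 with ATN1 (chromosome 12, 6922841 to 6926975, 4135 bp), SMC6 with GEN1 (3307 bp), NFATC4 (3170 bp), SDC1 (3099 bp), EDIL3 (2781 bp), C16orf74 (2770 bp), GCHFR with DNAJC17 (2767 bp), MED15 (2617 bp) and SNX25 (2586 bp). Wide PA-only peaks lay at GAREM1 (chromosome 18, 32469289 to 32471081, 1793 bp), HOXD8 (1773 bp), CLDN23 (1616 bp) and FGF9 (1506 bp). At CA9 the WT-only peak (chromosome 9, 35673321 to 35674253) lay at the place of the hypoxia-only H3K27ac peak, and the gene held no endogenous ZHX2 peak.

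Of the hypoxia ZHX2 peaks 54.2% (53.6 to 54.7%) overlapped a WT Flag peak, 27.1 times the mean of 1000 random placements, and 44.2% (43.6 to 44.7%) a PA Flag peak, 31.1 times (one-sided permutation of positions, p = 0.000999 each, the smallest possible). Of the hypoxia-only ZHX2 peaks 48.6% (47.97 to 49.2%) overlapped a WT Flag peak, against 68.9% (67.96 to 69.9%) of shared hypoxia ZHX2 peaks (odds ratio 0.426, 0.405 to 0.449, exact adjusted p = 3.34e-240, two-sided Fisher exact test), and within deciles of the score the odds ratio was 0.897. The share of hypoxia-only peaks was 1.87 times the mean of 100 placements within the merged regions of all lists. Of the 16679 hypoxia-only peaks that lay on H3K27ac 65.1% did so, against 34.6% for placements within H3K27ac regions, and of the 6786 others 8.13%. With peaks on H3K27ac reduced to 200 bp, 63.6% of hypoxia-only ZHX2 peaks (62.8 to 64.3%) overlapped a WT Flag peak, as did 63.6% of hypoxia-only CTCF peaks (61.4 to 65.8%), with 89.5% of those with a ZHX2 peak (87.2 to 91.4%) and 41.5% of those without one (38.5 to 44.7%). WT-only Flag peaks overlapped endogenous ZHX2 in 21.8% of cases, CTCF in 24.6% and H3K27ac in 59.4%, and shared Flag peaks in 69.5%, 61.9% and 86.1% (odds ratios 0.122, 0.116 to 0.129; 0.201, 0.191 to 0.211; and 0.236, 0.223 to 0.250). With peaks reduced to 200 bp these odds ratios were 0.340, 0.472 and 0.444. PA-only peaks gave 26.1%, 25.6% and 54.3%. WT-only peaks were narrower than shared ones, with a median of 436 bp against 1575 bp. As a whole, 42.6% of WT peaks overlapped CTCF and 72.3% H3K27ac, and 59.9% and 84.4% of PA peaks did so. These shares were 8.60, 12.0, 9.42 and 12.2 times those of random placement (permutation p = 0.000999 each). Within the merged regions of all lists the WT shares at CTCF and H3K27ac were 0.984 and 1.07 times the placed mean, and the PA shares 1.26 and 1.22 times.

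In the WT list hypoxia-induced genes held a peak at 34 of 36 members (94.4%, odds ratio 12.1, exact adjusted p = 1.05e-05, two-sided Fisher exact test, and 0.0153 against matched genes), and in the PA list at 30 (83.3%, exact adjusted p = 0.000292, and 0.0900 against matched genes). They were not alone in this. Cytosolic ribosomal protein genes held a WT peak at 79 and a PA peak at 78 of 81 members (exact adjusted p = 0.00817 and 3.40e-05 against matched genes). Replication-dependent histone genes, whose neighbours can hold the same peak, had 60 and 59 of 68 (exact adjusted p = 0.0343 and 0.000504 against matched genes). All 26 cell cycle genes held a WT peak (exact adjusted p = 1.06e-05, and 0.163 against matched genes) and 18 a PA peak (exact adjusted p = 0.126). Clustered protocadherins held few Flag peaks, 9 of 53 in the WT list (exact adjusted p = 7.13e-09) and 1 of 53 in the PA list (exact adjusted p = 5.10e-14). Gamma members share an annotated end and are not independent here either, and nor are neighbouring HOX genes. HOX genes held 13 and 12 of 39 (exact adjusted p = 0.00535 and 0.0349, 0.425 and 0.721 within 3 kb, and 0.111 and 0.528 against matched genes). Among invasion and matrix genes SNAI1, FN1, ITGA5, ITGA6 and CD44 held a WT peak alone. All 17 looping genes held a peak in both lists (exact adjusted p = 0.000792 and 7.37e-05, and 0.317 and 0.0807 against matched genes). Whether any list differed between WT and PA was not tested.

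At the genes followed in every list, ZHX2 itself (chromosome 8, 122780379 to 122974510) held peaks in all 8 lists, with a best ZHX2 fold of 10.2 in the normoxia list and 28.6 in the hypoxia list. CTCF, VHL, VEGFA, SLC2A1, CCND1 and HIF1A also held peaks in all 8. EPAS1, NDRG1, MYC and GATA3 held a ZHX2 peak in the hypoxia list alone, at folds of 4.16, 5.65, 4.37 and 2.41. CCND1 held ZHX2 peaks in both lists, with best folds of 3.91 and 4.59. EPAS1 and GATA3 held a Flag peak in the WT list alone. EGLN3 held no endogenous ZHX2 peak at its ends but WT and PA Flag peaks, and its CTCF peak was in the normoxia list alone (fold 4.74). ESR1, the oestrogen receptor gene, held H3K27ac in both conditions (folds 25.5 and 23.7) and no ZHX2, CTCF or Flag peak at its ends, while 11 hypoxia and 0 normoxia ZHX2 peaks lay inside the gene. HIF1A held 1 ZHX2 peak at its ends in each condition (folds 2.48 and 4.52), apart from the group of strong peaks inside the gene.

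**Figure D4:**
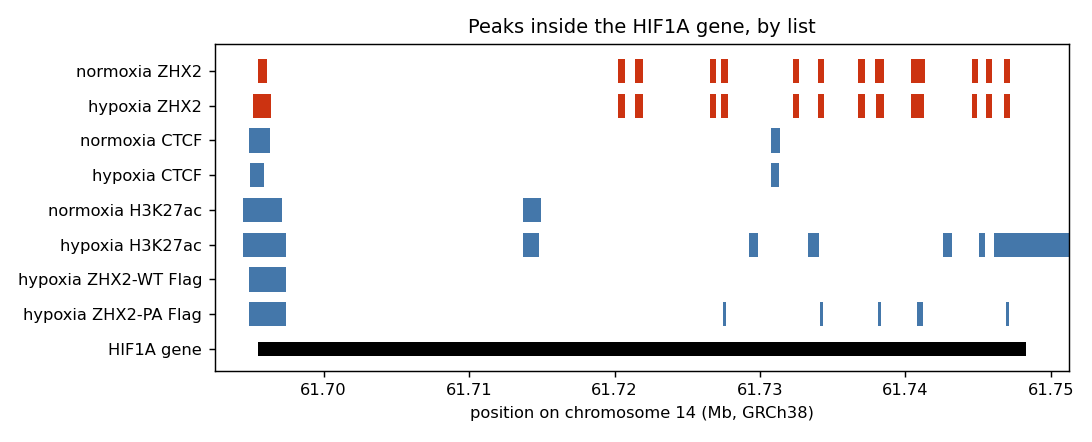
Position of the peaks of each list inside HIF1A (chromosome 14, 61695513 to 61748258; x axis in Mb of GRCh38); red boxes are endogenous ZHX2 peaks, blue boxes those of the other lists, and the black bar is the gene. The 12 strong ZHX2 peaks have the same places in normoxia and hypoxia, and the 5 PA Flag peaks inside the gene that are absent from the WT list lie on them.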

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

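All alternatives were chosen before the data were examined, with exceptions chosen after. These were leaving out peaks in HIF1A, NAT10 and antigen receptor segments, the placements within H3K27ac regions, and the comparison of 200 bp cores with hypoxia-only CTCF peaks. No paired analysis was possible because each group has 1 peak list and no columns per replicate, and for the same reason no replicate could be left out. Alternatives by score could not be run on the Flag lists, which have no score, and motif alternatives were not run without a genome. Depth is unknown, so weak peaks missing from a list cannot be separated from absent ones. All 60 named gene peaks kept their class in 120 values, and 11 of 19 change classes kept direction and side of the threshold throughout. The 4 endogenous and Flag overlaps stayed above random placement on their chromosomes in 14 values, which does not test whether the shares were stable. Of 264 gene list values, 200 kept their call, 41 lost it and 9 gained it. Without the HIF1A, NAT10 and receptor peaks the shared ZHX2 share was 27.4% in hypoxia and 62.6% in normoxia. Unless the construction of an alternative gives it (fewer or shorter peaks), the cause was not tested.

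At a −log10 q of at least 5 the normoxia ZHX2 list held 9132 peaks. For the shares of hypoxia ZHX2, normoxia ZHX2, hypoxia CTCF, hypoxia H3K27ac and normoxia H3K27ac peaks that were shared, overlap of 50% of the shorter peak gave 26.0%, 59.6%, 92.8%, 79.4% and 87.7%. In the order hypoxia then normoxia for ZHX2, CTCF and H3K27ac, summits or midpoints within 250 bp gave 23.1% and 51.2%, 91.2% and 79.96%, 58.9% and 64.6%. The upper 50% of both lists by score gave 29.4% and 66.5%, 98.9% and 87.5%, 87.6% and 96.0%. The upper 50% of the first list gave 43.0% and 78.4%, 99.98% and 99.99%, 98.9% and 99.9%. Lists of equal length gave 45.6% and 48.3%, 89.0% and 89.1%, 85.1% and 86.2%. Placement in the merged regions of all lists gave ratios of 0.907 for normoxia ZHX2 at H3K27ac and 0.984 for WT Flag at CTCF, both turned from above 1. The placed means were 62.5% and 43.3%, so these ratios compare with other peak regions and not with random chromosome positions.

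The odds ratios for hypoxia-only ZHX2 at H3K27ac turned to 1.39 (upper 50% of both lists), 1.30 (upper 50% of the first list), 1.38 (equal length) and 1.61 (score strata), and lost the threshold at 0.961 (summits or midpoints within 250 bp) and 0.983 (200 bp). Hypoxia-only CTCF at ZHX2 turned to 1.51 (summits), 1.69 (equal length) and 1.495 (200 bp) and lost it at 0.352 (upper 50% of the first list). Hypoxia-only CTCF at H3K27ac turned to 0.553 (upper 50% of both lists) and 0.591 (score strata). Normoxia-only CTCF at ZHX2 turned to 1.12 and 4.43 (upper 50% of both lists, of the first list). Normoxia-only CTCF at H3K27ac turned to 1.41 (upper 50% of both lists) and lost the threshold at 0.304 (upper 50% of the first list) and 0.945 (200 bp). Hypoxia-only H3K27ac at CTCF gave 0.773 (upper 50% of the first list, threshold lost) and turned to 1.13 (score strata). Normoxia-only H3K27ac lost it at 0.148 (ZHX2, upper 50% of the first list), 0.991 (ZHX2, score strata) and 0.853 (CTCF, upper 50% of the first list).

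With a 3 kb window, and with the ends of all annotated genes, the shares of peaks near a gene end were 50.0% and 48.1% (normoxia ZHX2), 47.2% and 45.1% (hypoxia ZHX2), 22.7% and 21.0% (normoxia CTCF), 23.8% and 22.4% (hypoxia CTCF), 30.5% and 29.3% (normoxia H3K27ac), 29.2% and 27.7% (hypoxia H3K27ac), 45.1% and 41.3% (WT Flag), 58.9% and 58.3% (PA Flag). The gene lists past the threshold against genes matched for normoxia H3K27ac were 4 for normoxia ZHX2, 2 for hypoxia ZHX2, 3 for hypoxia CTCF, 0 for normoxia H3K27ac (fixed by the matching), 2 for hypoxia H3K27ac, 6 for WT Flag and 5 for PA Flag, and with a 3 kb window 2 for hypoxia CTCF. These counts include lists below matched genes. For hypoxia ZHX2 they were zinc finger genes and olfactory receptors (odds ratios 0.564 and 0.118), so no list passed above matched genes. Those lists were also below for normoxia ZHX2, WT Flag and PA Flag, as were clustered protocadherins for WT and PA Flag. Matching turned zinc finger genes to odds ratios of 0.564 (hypoxia ZHX2), 0.414 (WT Flag) and 0.469 (PA Flag) and ribosomal protein genes to 0.809 (normoxia CTCF) and 0.8998 (hypoxia CTCF), and the 3 kb window turned HOX genes to 3.25 (normoxia CTCF). By peak midpoints, 31.1% of overlapping normoxia and 31.4% of overlapping hypoxia ZHX2 peaks lay within 100 bp of CTCF.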

Other observations

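The tests on HIF1A and on the number of ZHX2 peaks were chosen after the results were seen. The test on lymphocyte genes, and the overlap of receptor segment peaks with CTCF and H3K27ac, were fixed before their values were seen, though the receptor peaks themselves had been noticed. Genes in the next paragraph were also chosen after their values were seen.

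The most hypoxia-only ZHX2 peaks inside 1 gene were found in GSE1; counts were not tested against gene length. GSE1, a chromatin-associated coiled-coil protein gene on chromosome 16 (85169512 to 85676200), held 47 hypoxia-only ZHX2 peaks among 91 in hypoxia, with 68 in normoxia, 55 WT Flag and 26 PA Flag peaks. Hypoxia-only peaks were thus a smaller part of the hypoxia peaks in GSE1 than of the whole hypoxia list (72.55%). BCOR, the gene of a BCL6 corepressor on chromosome X, held 21 hypoxia-only peaks in 126 kb, 16 WT and 10 PA peaks. ANKRD11 held 18, CBFA2T3 18, MED13L 17, and DLG2, KDM4B and RASA3 16 each. MED13L held 16 WT and 2 PA Flag peaks, DLG2 2 and 0, KDM4B 9 and 2, and RASA3 12 and 7. Inside NAT10, on chromosome 11 (34105629 to 34146908), the hypoxia H3K27ac list had 16 peaks and the normoxia list 1, and 8 of the 16 were in the top percent by score, with folds of 28.4 to 60.2 and widths of 291 to 1574 bp against a median of 5804 bp for that top percent. NEK9 held a ZHX2 peak with a fold of 133 in the normoxia list and 61.7 in the hypoxia list, and no Flag peak.

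HIF1A held 12 strong narrow ZHX2 peaks at the same places in normoxia and hypoxia. If ZHX2 were bound to chromatin in the HIF1A gene, the WT Flag list should hold these peaks as it holds others of the top percent, but it held 0 of 12 against 286 of 313 (91.4%, two-sided Fisher exact test, p = 1.66e-12), which argues against that explanation; the PA Flag list held 5 of 12 against 266 of 313 (85.0%, p = 0.000985). Extra copies or uneven mapping of the HIF1A gene should appear with other antibodies, and 0 of the 12 overlapped a CTCF peak of either condition or a normoxia H3K27ac peak, while 2 overlapped a hypoxia H3K27ac peak. A candidate explanation is DNA copies of spliced HIF1A sequence in the libraries. Of the 5 PA Flag peaks in HIF1A that the WT list lacks, 5 lie on these ZHX2 peaks. ZHX2 binding or any other source of signal at these places would give that overlap too, so it does not separate them. The candidate stays open because exon positions were not used here.

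Normoxia-only ZHX2 peaks lay at immunoglobulin genes and T cell receptor genes, led by IGHV2-26 (chromosome 14, 106301396 to 106301739, fold 155), IGKC (chromosome 2, 88857238 to 88857756, fold 63.1) and IGHG1 (chromosome 14, 105741468 to 105742251, fold 60.3), which were the 3 highest folds among normoxia-only peaks. Extra copies or uneven mapping of the immunoglobulin genes should give peaks with other antibodies, but 3 of the 24 peaks overlapped a normoxia CTCF or H3K27ac peak. Reads from lymphocyte RNA copied to DNA could place such peaks, and the normoxia-only peaks at CD74 (fold 9.71) and at ACTB and GAPDH might have the same source. Of 10 further lymphocyte genes, including HLA-DRA, JCHAIN and CD79A, 0 held a normoxia-only ZHX2 peak inside the gene, against 11.7% of other protein-coding genes (one-sided Fisher exact test, p = 1). With about 1 gene expected among 10 the count decides nothing, the fixed immune and stromal list held ZHX2 peaks at 1 of 16 genes in normoxia, and contamination and another origin cannot be told apart.

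The ZHX2 list was longer in hypoxia by 2.22 times. A higher yield of peaks in every hypoxia library is argued against by the CTCF and H3K27ac lists, whose ratios were 0.876 and 1.10. Per the labels the ZHX2 samples had inputs of their own, and these ratios do not test a higher yield of the hypoxia ZHX2 libraries alone. For the 16679 hypoxia-only peaks on H3K27ac the WT Flag list held 65.1%, against 34.6% for 100 placements within H3K27ac regions (permutation p = 0.00990, the smallest possible), which argues against background spread evenly over those regions; it held 8.13% of the 6786 others and 11.8% (11.0 to 12.7%) of normoxia-only peaks. ZHX2 sites and background at open sites within active chromatin cannot be told apart, because the list held 63.6% of the 200 bp cores of these peaks and also of hypoxia-only CTCF peaks on H3K27ac, and splitting the latter into those with (89.5%) and without (41.5%) a ZHX2 peak selects them by the ZHX2 list itself. Lower sensitivity of the normoxia ZHX2 list could leave weak sites out of it, as 98.8% of the top percent of the hypoxia list was shared, but 37.4% of the normoxia list was not found in hypoxia, and without replicate values or depth this and a gain of ZHX2 in hypoxia cannot be told apart. Of these normoxia-only peaks 13.8% lay on CTCF and 21.4% on H3K27ac, far below shared normoxia peaks. How many of them are ZHX2 sites is therefore unknown.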
